A study of Danio rerio with 2 samples.

How the data were processed

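Total RNA from adult kidneys of Tg(actb2:KIT-D816V) and wild-type AB zebrafish was amplified to aRNA from 1 µg, coupled to AlexaFluor dyes, and hybridised in pairs, per the labels' protocols. The labels call these dyes Cy3 and Cy5. The design text states 1 pool of 3 kidneys per genotype and a dye swap of the same RNA. Whether the 3 kidneys came from males or females is not given in the sources used here.

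The authors deposited 1 scanner file per array. Per the file headers, the arrays were scanned at 532 and 635 nm and quantified with GenePix Pro 5.0.0.51, with local background and without normalization. The deposited values used here are foreground and background intensities per spot, not background-subtracted, together with the percent of saturated pixels and a spot flag score, 0 where unflagged. The 32 header lines of the 2 files were identical, and the arrays held positions 1 and 3 of the same slide, so slide and scan did not differ between them.

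The authors also deposited a table of processed log2 ratios for the same arrays, whose method is not given in the sources used here. Set against the scanner values, its columns correlated with the log2 ratio of 635 over 532 nm with r = 0.941 and 0.991, so they run in that direction and not by genotype. The columns correlate with each other with r = -0.912, as a dye swap would give. They differ from the raw log2 ratios by an offset that changed with intensity, from 0.80 in the dimmest class to -0.30 in the brightest of 10 classes on the array with KIT-D816V in Cy3, and from 0.30 to 0.17 on the other. The column medians are -0.08 and -0.01, and how they were centred stays unknown. Of 43663 rows, 21481 hold values, and these are the ones with a spot of flag 0 on each array. Who set the flags is not stated. After turning both columns to KIT-D816V over wild-type, they correlated with the values computed here with r = 0.998 and 0.997.

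From the scanner files, the mean foreground was corrected with normexp on the median local background with an offset of 50, and each array was normalized by loess with a span of 0.3, with control spots at weight 0 (limma 3.58.1, R 4.3.3). Log2 ratios were turned to KIT-D816V over wild-type, spots of 1 probe were averaged, and the mean of the 2 arrays was taken. The offset of 50 draws ratios of dim probes towards 0. A probe counted as detected in a channel when its foreground exceeded the local background median by 2.6 background SDs, since the scanner software gives no such flag per channel. The size rule, fixed before the data were examined, called a probe when it differed at least 2-fold the same way on each array and was detected on both arrays in the brighter genotype. No test was run, because there was 1 pool per genotype. Intervals for shares of control spots are 95% exact binomial and cover counting error only. Bootstrap intervals resample probes, taken as independent, and do not cover differences between hybridisations or pools.

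The rule for naming genes asked for the 12 highest and 12 lowest named genes past the size rule, members of fixed lists, and kita, kitb, kitlga, kitlgb and actb2. None of the 43603 probe names was found in the gene tables used here, so this rule, the gene lists, the medians of lists and the rule for several probes of 1 gene were not run. In their place the 2 highest and 2 lowest probes past the size rule are named, both of the lowest with saturated pixels on 1 array. Coordinates and annotations of the probes are not given for the same reason.

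The procedure was tested on simulated data for this comparison, with 43603 probes, an SD of 0.26 per array on the log2 scale and 50 probes changed at each of 4 folds. It called 0 of 50 probes at 1.5-fold, 5 of 50 at 2-fold, 41 of 50 at 4-fold and 48 of 50 at 8-fold, with no wrong direction. Of 32864 unchanged measured probes, 0 were called. The simulated noise had the same SD for every probe and was independent between the arrays. It held no dye effect particular to a probe and no signal raised on 1 array only. The 0 calls therefore give no error rate for the real arrays. The median fitted fold of probes changed 8-fold was 5.48. Alternatives planned beforehand changed the background correction, normalization, filter, saturated spots, size, source of values and array used. The processed table also holds fewer probes, so that setting changed the values and the probes together. Others added after seeing the data changed the loess span, the foreground statistic, the flags, the detection limit and the rows used.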

Results

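Adult zebrafish kidneys carrying the KIT-D816V transgene were compared with wild-type AB kidneys on oligonucleotide microarrays. KIT is a receptor tyrosine kinase of blood and mast cell precursors, and D816V is an activating change in its kinase domain. The transgene is driven by the promoter of actb2, a cytoskeletal actin gene. The adult zebrafish kidney also holds the marrow in which blood cells form. The comparison asks which transcripts differ in this organ between transgenic and wild-type fish aged 18 to 24 months.

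One RNA pool per genotype was prepared, each from 3 kidneys, and the same pair of pools was hybridised to 2 arrays with the dyes exchanged. On one array the KIT-D816V RNA carried Cy3 and the wild-type RNA carried Cy5. On the other array the dyes were the other way round. The 2 arrays are therefore a technical repeat of 1 biological sample per genotype. The values given after ± are the distance of each array from the mean of the 2. They cover labelling and hybridisation within 1 slide and scan only. There is no replicate check between animals, and no p-value is given.

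Each array held 45220 spots, of which 1417 were controls, and the remainder carried 43603 different probes. The median foreground intensity of the probe spots was 278 for KIT-D816V and 177 for wild-type on the array with KIT-D816V in Cy3. It was 151 for KIT-D816V and 176 for wild-type on the array with KIT-D816V in Cy5. Local background medians lay between 32 and 35. A total of 30808 probes, 70.7% of those on the array, were above the detection limit in at least 1 genotype on both arrays and are called measured. In both genotypes, 27165 probes passed on both arrays. A limit set from the negative control spots of all rows, added after seeing the data, left 23756 measured probes. The shares of measured probes given below use the 30808.

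The deposited arrays name probes and not genes, and none of the probe names occurs in the gene tables used here. The results are therefore given for probes, and several probes may stand for 1 gene. The gene lists chosen beforehand for blood lineages, nephron segments and pathways could not be applied. The transgene is human KIT, so no probe value checks the genotype labels either, and the direction of every difference rests on the dyes stated in the labels.

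The kidney transcriptomes of the 2 pools differed widely. Among the 30808 measured probes, 2547 (8.27%) were at least 2-fold higher in KIT-D816V on both arrays, and 1808 (5.87%) were at least 2-fold lower. A smaller group differed by much more, with 405 probes at least 4-fold higher and 203 at least 4-fold lower. At 8-fold on each array, 168 probes were higher and 59 were lower. The mean of the 2 arrays lay within 1.5-fold of equality for 18996 probes, or 61.7% of those measured.

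Nearly all differences past 2-fold on both arrays followed the RNA and not the dye. Only 1 probe, A_15_P475430, passed 2-fold on both arrays in opposite directions, at a log2 ratio of KIT-D816V over wild-type of 1.11 with KIT-D816V in Cy3 and -1.20 with KIT-D816V in Cy5. It was named after its values were seen, as the only such probe. There were 42 such probes with median centring in place of loess and 10 with plain background subtraction. At 1.5-fold on each array, 55 probes went in opposite directions. Of all measured probes, 85.5% had the same sign on both arrays. Across measured probes the log2 ratios of the 2 arrays correlated with Pearson's r = 0.912 and Spearman's rho = 0.883. This is a correlation across probes, which are not independent replicates. The SD of an array's deviation from the mean of the 2 was 0.18 on the log2 scale, against an SD of 0.85 for the mean log2 ratio. A further 3158 probes passed 2-fold on 1 array only and are not counted.

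**Figure D1:**
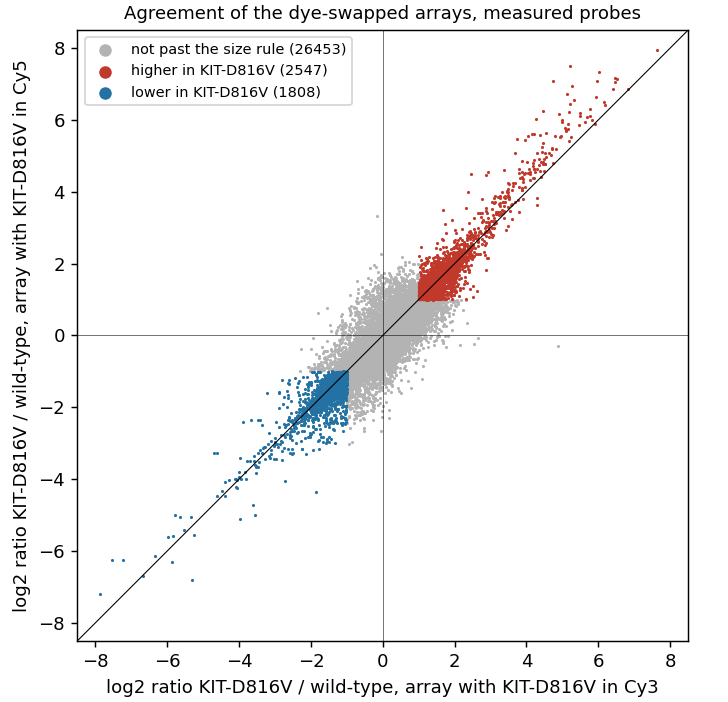
Log2 ratio of KIT-D816V over wild-type for each measured probe on the array with KIT-D816V in Cy3 (x axis) and on the array with KIT-D816V in Cy5 (y axis), with the line of equality. The 2547 probes higher and 1808 lower by the size rule, which demands the same direction on both arrays, lie near the line. Across all measured probes r is 0.912.

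The share of higher probes grew with the size of the difference up to 16-fold. Higher probes made up 54.7% of the calls at 1.5-fold on each array, 58.5% at 2-fold, 66.6% at 4-fold, 74.0% at 8-fold and 79.4% at 16-fold. At 32-fold the share was 72.3%, from 34 higher and 13 lower probes. Without loess, with each array only centred on its median, the calls at 2-fold were 1731 higher and 1786 lower, a share of 49.2%. At 8-fold that setting gave 159 higher and 52 lower.

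**Figure D2:**
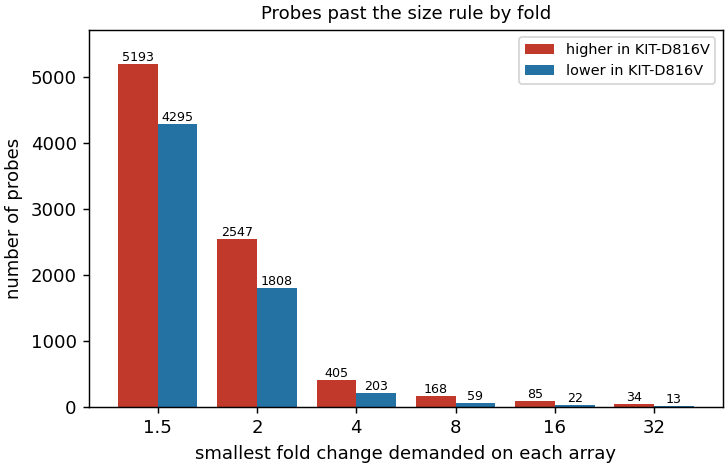
Number of probes (y axis) that were higher or lower in KIT-D816V by at least the given fold on each of the 2 arrays (x axis). Higher probes outnumber lower probes at every fold, from 5193 against 4295 at 1.5-fold to 34 against 13 at 32-fold.

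The 2 probes with the highest ratios were A_15_P432605 and A_15_P121142. A_15_P432605 had a log2 ratio of 7.79 ± 0.16, a 221-fold higher signal in KIT-D816V, with foreground intensities of 53161 and 36130 in KIT-D816V against 211 and 169 in wild-type. A_15_P121142 had a log2 ratio of 6.85 ± 0.02, a 116-fold higher signal in KIT-D816V. The 2 probes with the lowest computed ratios were A_15_P102730 and A_15_P629796. Their wild-type signal was saturated on the array with KIT-D816V in Cy5, in 72% and 91% of the spot's pixels, so their ratios there are limits and their rank is not exact. On the array with KIT-D816V in Cy3, where neither had a saturated pixel, the log2 ratio was -7.88 for A_15_P102730, with a foreground of 96 in KIT-D816V against 20098 in wild-type, and -7.54 for A_15_P629796, with 252 against 43936. On the saturated array the computed log2 ratios were -7.19 and -6.25. All 4 were above the detection limit in both genotypes on both arrays. Over the alternative settings the fold ran from 188 to 293 for A_15_P432605 and from 102 to 148 for A_15_P121142, neither of which had a saturated pixel.

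Some probes were detected in one pool alone. On both arrays, 416 probes were above the detection limit in KIT-D816V and below it in wild-type, and 218 were above it in wild-type and below it in KIT-D816V. Of these, 59 and 52 also passed the size rule, and most did not. The ratio of a probe detected in 1 pool alone has only a lower bound, because the dim genotype was not well above background. The 416 and 218 leave out probes whose other genotype passed the limit on 1 array. On the array with KIT-D816V in Cy3, negative control spots passed the limit more often for KIT-D816V (42.5%) than for wild-type (25.5%). A probe was thus harder to count as absent from KIT-D816V there, so 416 against 218 does not measure a difference between the genotypes. Over all probes, 28702 were detected on both arrays in KIT-D816V and 29271 in wild-type. This order cannot be read as a difference between the genotypes, because the order on each array followed the dye. With KIT-D816V in Cy3, 85.7% of probe spots passed the limit in KIT-D816V and 76.6% in wild-type. With KIT-D816V in Cy5, 66.4% passed in KIT-D816V and 71.7% in wild-type.

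Calls were unevenly spread over signal intensity. When measured probes were ordered by mean intensity and cut into 10 classes of equal size, 0.227% of the dimmest class were higher and 0.519% were lower. The offset of 50 draws ratios of dim probes towards 0, so the low shares there are partly set by the processing. In the eighth class, 15.6% were higher and 8.28% were lower. In the brightest class, 8.70% were higher and 7.85% were lower. The 2 orientations disagreed most in the brightest class, where the SD of the deviation from their mean was 0.29 against 0.20 in the next highest class.

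**Figure D3:**
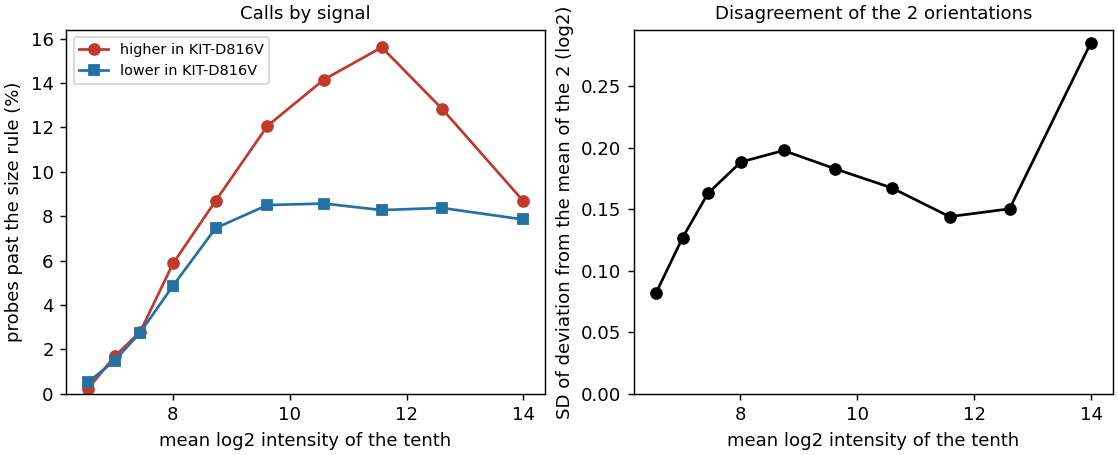
Left, share of measured probes past the size rule (%) in 10 classes of mean log2 intensity, with lines for higher and lower probes; right, SD of an array's deviation from the mean of the 2 (log2) in the same classes. The share of higher probes peaks at 15.6% and the SD is highest, 0.29, in the brightest class.

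Spots printed more than once gave the error within an array. Among 50 probes printed 5 times each, 26 were measured. The median SD of the log2 ratio over their spots was 0.11 on the array with KIT-D816V in Cy3 and 0.07 on the other. Both lie far below the log2 difference of 1 that the size rule demanded.

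The negative control spots showed that the 2 arrays differed in quality. On the array with KIT-D816V in Cy3, 65 of 153 such spots in the Cy3 channel and 39 of 153 in the Cy5 channel exceeded the detection limit, or 42.5% (95% exact interval 34.5% to 50.7%) and 25.5% (18.8% to 33.2%). On the other array, 2 of 153 did so in each channel, or 1.31% (0.159% to 4.64%). The signal was strongest in rows 1 to 34 of the affected array, where the median negative control was 209 in Cy3 and 141 in Cy5, against 41.5 and 40.5 in rows 35 to 68 and 46 and 43 in rows 69 to 170. On the other array it was 30 in Cy3 and 33 in Cy5 in all 3 bands. Rows 1 to 34 held 6326 measured probes, of which 7.33% were higher and 4.63% lower. In rows 35 to 68, 8.97% were higher and 5.92% lower. In rows 69 to 170, 8.35% were higher and 6.28% lower.

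**Figure D4:**
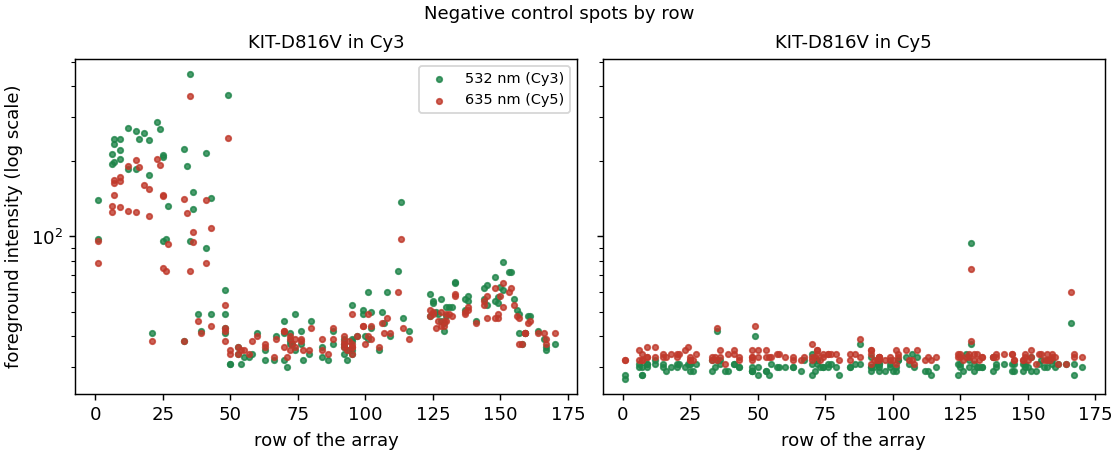
Foreground intensity (log scale) of 153 negative control spots per array against the row of the array, in the Cy3 and Cy5 channels. The array with KIT-D816V in Cy3 has raised values in its first rows, with a median of 209 in Cy3 over rows 1 to 34, and the array with KIT-D816V in Cy5 has a Cy3 median of 30 there.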

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

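The test on rows 1 to 34 was chosen after the result was seen.

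Negative control spots, which should stay dark, were read above local background on the array with KIT-D816V in Cy3. This was so for 42.5% of them in the Cy3 channel and 25.5% in the Cy5 channel, against 1.31% in each channel of the other array. Log2 ratios were also less spread on the affected array, in every one of the 10 intensity classes and not in dim probes alone. The ratio of SDs ran from 0.873 in class 3 to 0.979 in the brightest class, and was 0.935 in the dimmest. The test by rows used the dim probes (classes 2 to 5 of 10 by intensity) of the affected array. In its rows 1 to 34 their SD was 0.711 of that on the other array (95% bootstrap interval 0.694 to 0.728). The ratio was 0.911 (0.892 to 0.930) in rows 35 to 68 and 0.935 (0.923 to 0.946) in rows 69 to 170. These intervals resample probes, taken as independent, within 1 pair of arrays. Diffuse signal in rows 1 to 34 may account for the stronger compression there. It does not account for the whole pattern, because the ratio in rows 69 to 170 also stayed below the bound of 0.95 set beforehand. The median negative control in rows 69 to 170 was 46 in Cy3 and 43 in Cy5, above the 30 and 33 of the other array, and whether this weaker signal reduced the ratios there was not tested. No biological explanation was tested, since both arrays held the same RNA.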

How the results depend on the processing

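The choices named in this part as added were made after seeing the data. The size demanded set the counts most: 5193 probes higher and 4295 lower at 1.5-fold on each array, and 405 and 203 at 4-fold, against 2547 and 1808 at 2-fold. Ratios from either array alone, with detection still demanded on both, gave 3326 to 3503 higher and 2200 to 2835 lower probes. The 2835 came from the array with KIT-D816V in Cy5 (without replicate 1). Median centring without loess lowered the r between arrays from 0.912 to 0.807 and raised the probes with opposite signs from 1 to 42; it kept 1648 of the 2547 higher and 1408 of the 1808 lower calls. Plain subtraction with a floor of 1 gave 10 probes with opposite signs. For the single arrays, median centring and subtraction the cause was not tested. Leaving out rows 1 to 68, an added choice, left 1530 higher and 1150 lower, because fewer probes were tested. The other settings kept both counts within 1.5 times and r within 0.05. No setting turned a called probe to the opposite call, or changed the sign of the 4 probes named for the highest and lowest ratios; leaving out saturated probes removed both of the lower ones. A_15_P475430, not a called probe, changes sign between the single arrays. Aquantile alters intensities and not ratios, so its run says nothing. The authors' processed values, with 21425 measured probes, gave 2559 higher and 1705 lower, of which 2382 and 1600 were called here too. Of the calls, 2476 higher and 1694 lower were on probes unflagged on both arrays, an added choice. Gene list medians and the mean of a gene's probes were not run, since probes have no gene names here. Signal over background limited the measured probes to 30808 of 43603. A limit at the 95th percentile of the negative controls in each channel, an added choice, left 23756 measured probes. Of these, 2504 were higher and 1754 lower.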

Other observations

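The tests on single arrays and on further pools were chosen after the result was seen. The loess span of 0.05 was added after seeing the data but before its own result, and all patterns were found in the same data.

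Probes with very large differences were mostly higher in KIT-D816V, with 168 higher and 59 lower at 8-fold on both arrays. The ratio of these counts was 2.85. It stayed at 2.11 or more over the planned background corrections and normalizations, the lowest coming from plain subtraction with a floor of 1. This lies above the bound of 1.5 set beforehand, which argues against these choices as the cause. The ratio was 2.48 (exact interval 1.90 to 3.25, with probes taken as independent) on the array with the lower one. Each array's count includes the probes past 8-fold on both, which largely fixed this ratio. The test therefore cannot decide whether a single array or dye orientation was the cause. With the dyes exchanged, 0 probes passed 8-fold in opposite directions. With 1 pool per genotype, the genotype cannot be told apart from any other difference between the 2 pools, such as the fish chosen or neighbouring tissue taken along, and several probes may count the same gene.

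The brightest of 10 intensity classes disagreed most between the dye orientations, with an SD of the deviation from their mean of 0.29 on the log2 scale (bootstrap interval 0.28 to 0.29). Saturated pixels do not explain it, since the SD was 0.28 (0.27 to 0.29) without the 44 saturated probes among its 3081. With a loess span of 0.05 the SD was 0.23 (0.22 to 0.23), above the bound of 0.20 that would have accounted for it and below the bound for excluding it, so a dye curve left at high intensity may account for part of it, and the remainder stays open. The counts with that span were 2570 higher and 1868 lower, close to those of the wider span, and 2417 and 1689 of these were called with both. No biological explanation was tested, since both arrays held the same RNA.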
